A study of Danio rerio with 24 samples.

How the data were processed

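Skeletal muscle RNA of adult zebrafish (Danio rerio, 4 months old per the labels) was sequenced as stranded, poly(A)-selected paired-end Illumina libraries that were pooled before sequencing, per the labels' protocols. The groups were untrained wild-type fish (untrained_WT), wild-type fish after chronic exercise training (trained_WT) and untrained fish carrying a transgene written actc1b:PGC1alpha (untrained_TG). PGC1alpha is a transcriptional coactivator known for driving mitochondrial biogenesis, and actc1b is a muscle actin gene. The labels describe 24 samples, 8 per group, and 21 of them were analysed here, 7 per group. The authors' count table holds no column for untrained_WT replicate 1, trained_WT replicate 7 and untrained_TG replicate 8, so these were not analysed. The tests had been planned for 8 libraries per group and were run on 7. The labels call each sample a separate sample but do not say whether it was 1 fish or a pool, so p-values measure the spread between these samples.

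The authors deposited a table of raw read counts per gene for 31953 Ensembl gene IDs. The submitters' processing notes name STAR 2.4.0i, HTSeq 0.9.1, DESeq2 and the zebrafish build GRCz10. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may not be separable, and close paralogs are uncertain where multi-mapped reads were set aside. The authors also deposited tables of log2 fold changes with their standard errors, and of p-values with their adjusted values, for untrained_TG and for trained_WT each against untrained_WT. Those tables were used for gene symbols (31312 of the IDs were named, 641 were not, and 515 symbols were shared by more than 1 ID) and to compare counts of calls. Their normalised values per library were not used here. No reference genome was used, so no coordinates are given.

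Entries that name no gene were left out of library sizes. Reads without a feature came to 6.19% ± 1.01 (SD, n = 7) of all reads in the count table in untrained_WT, 5.79% ± 0.259 in trained_WT and 9.18% ± 0.577 in untrained_TG. Reads with more than 1 alignment came to 9.07% ± 1.05, 9.06% ± 0.861 and 6.65% ± 0.906. Counts over genes ranged from 42.8 to 79.2 M per library, and 4680 genes had no counts. No pair of libraries within a group agreed within sampling noise.

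Genes were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM scaling, filterByExpr by group and all 21 libraries in 1 fit with group as the only term. The filter left 18947 genes. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and an adjusted p under 0.05 counted as a call. The standard error of a log2 fold change is its size divided by the square root of F. Levels are CPM (counts scaled to TMM-adjusted library sizes), given as mean ± SD. The common biological coefficient of variation was 49.5%. Changes were planted in simulated counts, only in genes with a mean of at least 50 counts. Genes were drawn independently and without outlying libraries, so recovery and false calls may be worse in the real data. For untrained_TG versus untrained_WT, 51 of 100 planted changes of 1 log2 unit and 95 of 100 of 2 units were recovered, with 3 false calls over 18577 genes. For trained_WT versus untrained_WT these were 54 and 90 of 100 over 18649 genes, with 6 false calls. For untrained_TG versus trained_WT they were 55 and 91 of 100 over 18649 genes, with 3 false calls.

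Before the data were examined, 35 gene lists were fixed, along with the tests, most alternatives and the rule for named genes. Lists were tested with limma 3.58.1 on voom values, by camera with a preset correlation of 0.01, camera with the correlation estimated from the residuals, and fry. Camera compares a list with the other genes. Fry asks whether the genes of a list move, on balance, 1 way. Shares of counts were compared with exact two-sided permutation tests over all 3432 splits of 7 against 7, adjusted over 9 tests. The rule named, per contrast, called genes with a mean of at least 50 counts, a full gene symbol and every library of the first group on the same side of the median of the second, and of these the 8 highest and 8 lowest fold changes (5 and 5 for untrained_TG versus trained_WT). It also named the 3 members of each list with the smallest p in each comparison with untrained_WT, and ppargc1a and actc1b. The planned 7 of 8 libraries was applied as 7 of 7.

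Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, median-ratio (RLE) scaling, library totals only, no filter, only the libraries compared, the replicate number as a block, robust dispersion and, for shares, other denominators or medians. Alternatives added after seeing the data left out untrained_WT replicate 7, untrained_TG replicate 7 or both untrained_WT replicates 3 and 7, or used a germ-cell score (mean log2 CPM of ddx4, dazl and piwil1) as a covariate. For the count of trained calls, each untrained_WT library and each pair of them was also left out in turn. Chance values for comparisons that share controls came from 20 simulations of unchanged groups, and the 7 controls were divided 4 and 3 in 35 ways, in place of the planned 4 and 4. Other splits of the samples were drawn 100 times per contrast, the real split included.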

Results

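Polyadenylated RNA was counted per gene in skeletal muscle of 7 untrained wild-type, 7 trained wild-type and 7 untrained transgenic zebrafish samples. Untrained_WT libraries held 75.1 ± 2.66 M counts over genes (SD, n = 7), trained_WT libraries 75.3 ± 2.38 M and untrained_TG libraries 67.8 ± 12 M. In untrained_WT muscle the gene with the largest share of counts was the fast myosin heavy chain gene myhc4, at 6.57% ± 2.47 of all counts. In untrained_TG muscle it was mt-co1, the mitochondrially encoded subunit 1 of cytochrome c oxidase, at 15.7% ± 1.04. The first principal component took 32.9% of the variance and set all transgenic libraries apart from all wild-type ones. The second took 16.1% and spread libraries within groups, with untrained_WT replicates 7, 3 and 5 at 121.4, 89.1 and 59.7 and untrained_TG replicate 2 at 72 on 1 side, and trained_WT replicates 2 and 3 at -96.2 and -70.5 on the other. Of the trained_WT libraries, 5 of 7 lay below 0.

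The targeted genes were examined first. Zebrafish ppargc1a was at 16.8 ± 8.16 CPM in untrained_TG, 28.1 ± 16.3 in untrained_WT and 24.4 ± 11.2 in trained_WT (n = 7 each), with log2 fold changes of -0.74 ± 0.42 (SE, adjusted p = 0.168) and -0.20 ± 0.42 (adjusted p = 0.841) against untrained_WT. The labels do not say which species or part of PGC1alpha the transgene holds, so this count may not include it and does not check the genotype labels. The endogenous gene of the promoter, actc1b, fell from 24680 ± 10510 CPM to 3193 ± 577 in untrained_TG, a log2 fold change of -2.95 ± 0.27 (adjusted p = 1.13e-08).

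The comparison of untrained_TG with untrained_WT asks how the transgene changes the muscle transcriptome without training. Transcripts of the respiratory chain, of mitochondrial translation and of slow fibres rose, and those of fast fibres fell. Mitochondrially encoded genes took 46.8% ± 2.45 of counts in untrained_TG and 10.5% ± 2.38 in untrained_WT. All 13 rose, with a median log2 fold change of 3.03. The gene mt-nd6 rose by 4.88 ± 0.27 log2 units and mt-co1 by 2.26 ± 0.18. Because mt-nd6 is encoded on the opposite strand to the other members and the strand setting is not given, its count is uncertain. Nuclear-encoded oxidative phosphorylation genes took 7.35% ± 0.268 of counts against 3.05% ± 0.383. Both differences had an exact permutation p of 0.000583, the smallest this design allows, and an adjusted p of 0.000874 over 9 tests.

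**Figure D1:**
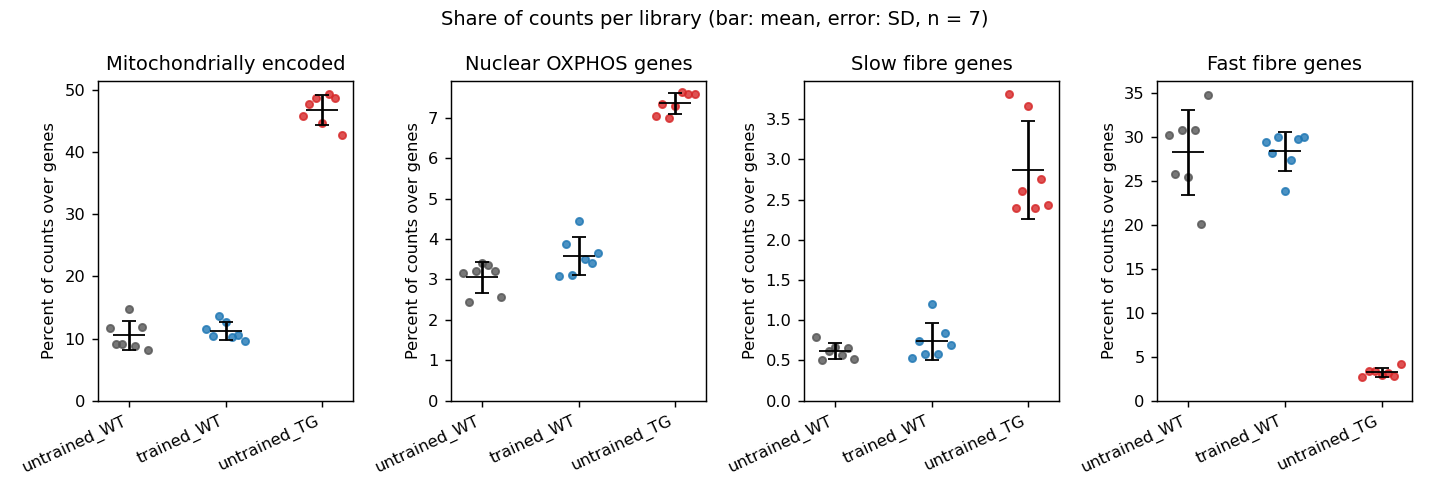
Percent of counts over genes per library (y axis, linear) for mitochondrially encoded, nuclear-encoded oxidative phosphorylation, slow fibre and fast fibre genes in the 3 groups (x axis). Points are libraries, horizontal bars are means and error bars are SD (n = 7). Every untrained_TG library lies outside the wild-type range in all 4 panels, as with mitochondrially encoded genes at 42.8% to 49.4% against 8.17% to 14.8% in untrained_WT.

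Every measured nuclear-encoded subunit in the lists of respiratory complexes rose in untrained_TG: 37 of complex I, 5 of complex II, 9 of complex III, 24 of complex IV and 16 of ATP synthase. Their list medians lay between 1.24 and 1.88 log2 units, and the counts adjusted over the list alone were the same. With an estimated correlation the adjusted p was 0.0719 for complex IV and 0.0973 for each of the other complexes, and it was 0.0843 for mitochondrially encoded genes. Fry called each of these lists higher, with an adjusted p of at most 1.04e-07. Examples are ndufb10 of complex I (2.02 ± 0.15), cox8b of complex IV (2.47 ± 0.15) and atp5g1, which encodes the c subunit of ATP synthase (2.85 ± 0.23). Within the complex IV list, ndufa4, which encodes a cytochrome c oxidase-associated protein, rose from 2.57 ± 0.695 to 418 ± 175 CPM, by 7.35 ± 0.38 log2 units (adjusted p = 4.03e-12). All 76 measured mitochondrial ribosomal protein genes rose, with a median of 1.24. Mitochondrial import had 20 of 25 higher and 3 lower. The citrate cycle list had 17 of 19 higher, among them the citrate synthase gene cs (1.60 ± 0.16) and pdha1a of pyruvate dehydrogenase (1.71 ± 0.15). By its symbol the list also took dld, which in zebrafish encodes a Notch ligand and no citrate cycle enzyme. Fatty acid oxidation had 24 of 28 higher, such as hadhb (1.82 ± 0.18), and branched-chain amino acid breakdown 19 of 20, such as bcat2 (2.54 ± 0.20) and mccc2 (2.50 ± 0.19). The mitochondrial superoxide dismutase gene sod2 rose by 1.54 ± 0.17, within an antioxidant list of 6 higher and 4 lower of 16 (fry adjusted p = 0.00185, camera adjusted p = 0.141, or adjusted p = 0.531 with an estimated correlation). For these lists the counts adjusted over the list alone were again the same. With an estimated correlation the adjusted p was 0.1 for mitochondrial ribosome, citrate cycle and branched-chain amino acid breakdown, 0.0973 for fatty acid oxidation and 0.206 for import. Fry called each of them higher, with an adjusted p of at most 1.03e-05.

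Slow fibre genes rose in 15 of 18 and fell in 1, with a median log2 fold change of 2.19. Myoglobin (mb) rose from 291 ± 85.5 to 3373 ± 896 CPM (3.54 ± 0.23), the slow troponin C gene tnnc1b rose by 3.37 ± 0.20 and the slow myosin gene smyhc1 by 2.23 ± 0.21. Slow fibre genes took 2.86% ± 0.61 of counts against 0.619% ± 0.099 (exact permutation p = 0.000583, adjusted p = 0.000874). Fast fibre genes fell in 28 of 34 and rose in 2 (28 and 3 adjusted over the list alone), with a median of -3.59. With an estimated correlation the adjusted p was 0.0973 for both fibre lists, and by fry it was 7.13e-10 for slow and 1.8e-10 for fast fibre genes. The myosin gene myhc4 went from 61060 ± 34170 to 50.1 ± 71.6 CPM (-10.25 ± 0.76), and the parvalbumin genes pvalb1, pvalb2 and pvalb3, which encode calcium buffers of fast fibres, had log2 fold changes of -9.40 ± 0.64, -8.81 ± 0.73 and -9.52 ± 0.62. The fast troponin I gene tnni2a.3 (-7.86 ± 0.46), the calcium release channel gene ryr1b (-3.67 ± 0.23) and the creatine kinase gene ckma (-1.70 ± 0.20) also fell. Untrained_TG replicate 7 held 212 CPM of myhc4, against 17.9 to 31.7 in the other transgenic libraries.

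Glycolysis and glycogen genes went both ways, with 16 of 22 lower and 6 higher, also when adjusted over the list alone (fry adjusted p = 0.019, camera adjusted p = 0.055, or adjusted p = 0.836 with an estimated correlation). Lactate dehydrogenase ldha (-3.85 ± 0.26) and the glycogen phosphorylase gene pygma (-2.36 ± 0.25) fell, while the paralog pygmb rose by 3.57 ± 0.38. Genes of the proteasome list fell in 33 of 40 (34 adjusted over the list alone), as with the subunit gene psmd3 (-1.47 ± 0.14). The adjusted p was 0.206 with an estimated correlation. The name pattern of that list also took psmc3ip, which encodes no proteasome subunit. Among ubiquitin ligases of muscle breakdown, fbxo32 (-2.99 ± 0.41), trim63a (-1.81 ± 0.34) and trim63b (-1.78 ± 0.23) fell, while the myostatin gene mstnb rose by 2.68 ± 0.26. That list had 8 of 14 lower and 2 higher, or 9 and 3 adjusted over the list alone (fry adjusted p = 0.019, camera adjusted p = 0.298, or adjusted p = 0.796 with an estimated correlation). Vascular genes rose in 15 of 22 (15 higher and 1 lower adjusted over the list alone, adjusted p = 0.206 with an estimated correlation), including vegfab (2.07 ± 0.22), which encodes a vascular growth factor, and its receptor gene kdrl (1.08 ± 0.27), whose call was lost with library totals only and with the germ-cell covariate. The list of PGC1alpha partners had 4 higher and 3 lower of 18, with pparab, a lipid-sensing nuclear receptor gene, at -2.50 ± 0.35. Its camera test pointed up while its median was -0.003 and its mean -0.081 (camera adjusted p = 0.635).

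In all, 8232 of 18947 genes were called, 3468 higher and 4764 lower. With the germ-cell score as a covariate 6178 were called, 2585 higher and 3593 lower. The score differed between these groups, as the closing section reports, so this fit cannot part germ-cell content from the transgene. With library totals as the only scaling, 15.9% of calls were higher instead of 42.1%, and the median over all genes moved from -0.135 to -0.644, which turned the sign of 10 list medians, none of them that of a mitochondrial, fibre, glycolysis, proteasome or vascular list. The lists that turned were antioxidant, myogenesis, cytosolic ribosome, interferon, matrix, red and white blood cell, adipocyte, nerve, and germ line and liver. By the naming rule the highest fold changes were cryaa (8.56 ± 0.69), a lens crystallin gene, then zic2b (8.10 ± 0.68), ndufa4, nmrk1 (6.90 ± 0.31), atp1b1b (6.61 ± 0.44), MPV17L (5.99 ± 0.74), mtbl (5.68 ± 0.41) and zp3d.1 (5.58 ± 0.24). The lowest, besides myhc4 and the parvalbumins, were the myosin gene myha (-10.21 ± 1.22) and tecrl2b, helt and TMEM233. Of these last, tecrl2b went from 7.78 ± 3.97 to 0.00253 ± 0.0067 CPM, helt from 3.02 ± 3.26 to 0.00603 ± 0.0105 and TMEM233 from 5.51 ± 2.52 to 0.0115 ± 0.0151, levels at which a fitted fold depends on the prior count. The same holds for the folds and the order of cryaa, zic2b and MPV17L, whose untrained_WT libraries averaged 2.43, 1.86 and 7.14 counts. The camera test called 15 lists, 13 higher and 2 lower, and fry 21, but none of the camera calls was left with an estimated correlation (smallest adjusted p = 0.0719). Other splits of the 14 libraries often gave as many camera calls, as the closing section reports, so the list statements here rest on the gene counts.

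**Figure D2:**
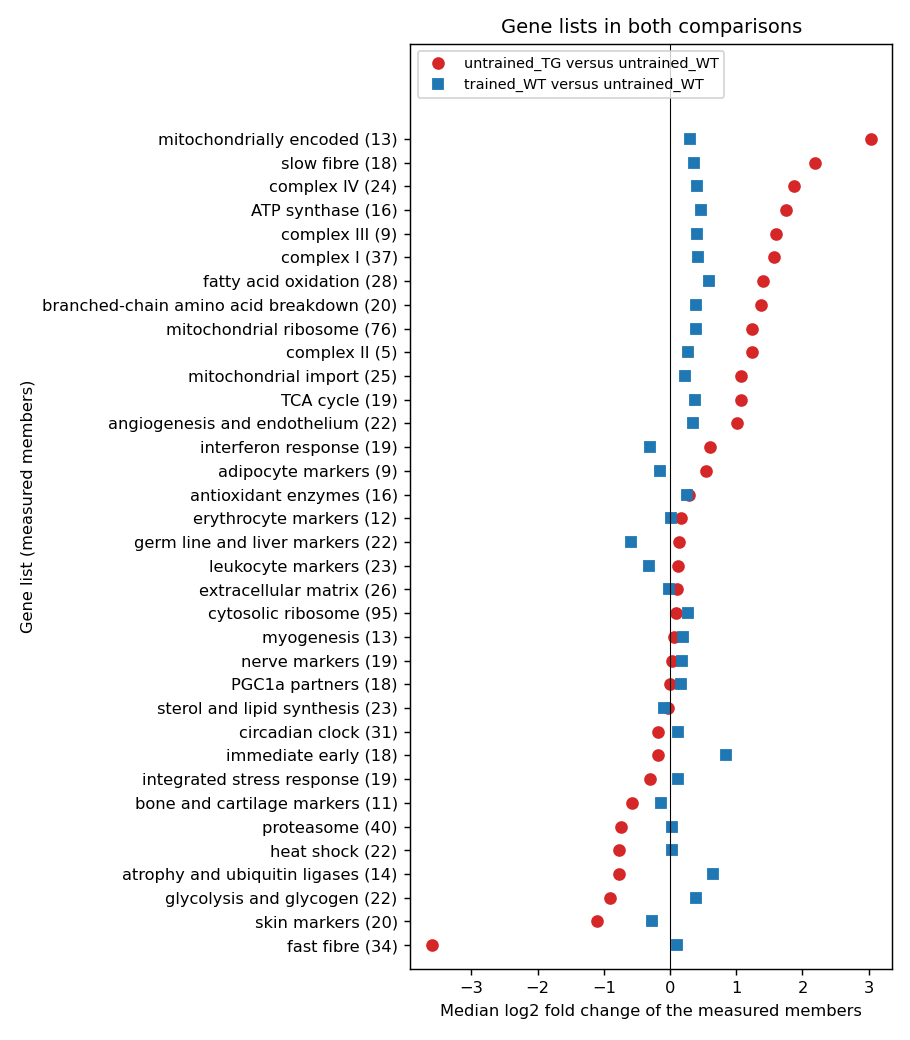
Median log2 fold change of the measured members (x axis) for each of the 35 gene lists (y axis, measured members in parentheses). Circles are untrained_TG versus untrained_WT and squares trained_WT versus untrained_WT, such as fast fibre at -3.59 and 0.11 and immediate early at -0.18 and 0.84. With library totals as the only scaling the sign turned for 10 list medians with untrained_TG and for 11 with trained_WT, fast fibre among the latter.

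Red blood cell, white blood cell, skin, nerve, bone and matrix markers had, in untrained_TG, 1 higher of 12, 4 higher and 3 lower of 23, 1 higher and 4 lower of 20, 3 higher of 19, 2 higher and 3 lower of 11, and 4 higher and 2 lower of 26. Adipocyte markers had 4 higher of 9 (fry adjusted p = 0.00134, camera adjusted p = 0.082, or adjusted p = 0.288 with an estimated correlation). Germ line and liver markers had 5 higher and 3 lower of 22, with a median of 0.131 but a mean of -0.141. Heat shock genes had 6 higher and 11 lower of 22, the integrated stress response 6 lower of 19, clock genes 3 higher and 6 lower of 31, and immediate early genes 1 higher and 4 lower of 18. Sterol and lipid synthesis had 3 lower of 23, interferon response 3 higher and 1 lower of 19, myogenesis 4 higher and 3 lower of 13, and cytosolic ribosome 6 higher and 11 lower of 95, of which 2 and 3 are S6 kinase genes and no ribosomal proteins. Adjusted over the list alone, counts changed for heat shock (12 lower), integrated stress response (4 lower), clock (2 higher), immediate early (3 lower), matrix (3 higher, 1 lower), skin (3 lower), nerve (2 higher) and cytosolic ribosome (4 higher, 8 lower). The camera test called none of the lists in this paragraph. Besides adipocyte markers, fry called the integrated stress response (adjusted p = 0.0217) and sterol and lipid synthesis (adjusted p = 0.049), both lower, with an adjusted p of 0.796 and 0.836 with an estimated correlation.

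The comparison of trained_WT with untrained_WT asks what differed in wild-type muscle after chronic exercise training. The time since the last exercise bout and the time of sampling were not examined, so lasting and short-lived changes are not separated. Trained muscle had higher transcripts of the orphan nuclear receptor nr4a3, of lipid uptake and oxidation genes and of the ubiquitin ligase gene trim63a. Some other muscle breakdown genes and some immediate early and myogenic genes were also higher. In all, 559 genes were called, 426 higher and 133 lower. The gene nr4a3 went from 3.97 ± 2.94 to 131 ± 44.7 CPM (log2 fold change 5.05 ± 0.61, adjusted p = 3.8e-05). Lipoprotein lipase lpl rose from 35.3 ± 15.0 to 154 ± 22.6 CPM (2.12 ± 0.28), eci1 by 0.95 ± 0.17 and acads by 0.93 ± 0.18, and fatty acid oxidation had 8 of 28 higher, or 21 adjusted over the list alone (adjusted p = 0.211 with an estimated correlation). The estrogen-related receptor gene esrra, an activator of oxidative metabolism genes, rose by 2.14 ± 0.42 and the fatty acid sensor gene pparaa by 1.08 ± 0.25.

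Most respiratory genes were not called after adjustment over all genes. Complex I had 4 of 37 higher (31 adjusted over the list alone), complex II 0 of 5 (0), complex III 0 of 9 (2), complex IV 1 of 24 (14), ATP synthase 1 of 16 (14), mitochondrially encoded genes 0 of 13 (1) and mitochondrial ribosome 5 of 76 (29). At an unadjusted p under 0.05 there were 1 in complex II, 5 in complex III and 3 among mitochondrially encoded genes, where DESeq2 called 0, 1 and 2 and limma 0, 0 and 1. With an estimated correlation the adjusted p was 0.315 or 0.389 for each of these lists. Fry called complex I (adjusted p = 0.0224), complex III (0.0342), complex IV (0.0163), ATP synthase (0.0262) and mitochondrial ribosome (0.0342) higher. It did not call complex II or mitochondrially encoded genes (fry adjusted p = 0.104 for each). List medians lay between 0.28 and 0.47 for the complexes, with ndufc2 at 0.57 ± 0.13, cox5ab at 0.78 ± 0.19 and mrpl22 at 0.66 ± 0.14. With library totals as the only scaling the medians of the 5 complexes lay between 0.06 and 0.26. Nuclear-encoded oxidative phosphorylation genes took 3.58% ± 0.472 of counts against 3.05% ± 0.383 (exact permutation p = 0.0379, adjusted p = 0.0487). With medians in place of means the difference was 0.311 percentage points (adjusted p = 0.0749). Mitochondrially encoded genes took 11.2% ± 1.45 against 10.5% ± 2.38 (exact permutation p = 0.502) and slow fibre genes 0.739% ± 0.228 against 0.619% ± 0.099 (p = 0.234 by the same exact test). Slow myosin genes moved apart, smyhc1 by 0.83 ± 0.20 and myh7ba by -1.26 ± 0.26. By edgeR 0 of 34 fast fibre genes were called, with 1 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma, and 0 of 22 glycolysis genes, with 6 at an unadjusted p under 0.05 and 0 by either other tool.

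Of the ubiquitin ligase and breakdown list, 4 of 14 rose (12 higher and 1 lower adjusted over the list alone, adjusted p = 0.0908 with an estimated correlation), among them trim63a from 387 ± 208 to 1529 ± 522 CPM (1.98 ± 0.34), klf15 (1.39 ± 0.32) and foxo4 (0.81 ± 0.19). Immediate early genes rose in 3 of 18 (10 adjusted over the list alone, adjusted p = 0.211 with an estimated correlation), such as junbb (1.97 ± 0.34) and dusp1 (1.06 ± 0.24). The stress gene ddit3 rose by 1.2 ± 0.16. Myogenic genes rose in 3 of 13, namely the myogenic factors myf5 (1.55 ± 0.40) and myf6 (1.2 ± 0.23) and the fusion gene mymk (3.90 ± 0.88). Adjusted over that list alone, 3 were higher and 1 lower (fry adjusted p = 0.0342, or adjusted p = 0.315 with an estimated correlation). Of the clock genes, per2 rose by 1.14 ± 0.20 and arntl1b fell by 1.05 ± 0.23. The endothelial genes kdrl (1.03 ± 0.27) and tek (0.85 ± 0.21) rose. The highest fold changes by the naming rule were aipl1 (5.47 ± 0.80), cldn15la (5.24 ± 0.80, from a mean of 4.57 counts in untrained_WT), nr4a3, actl6b (4.55 ± 0.39), SLC7A1 (1 of many) (4.24 ± 0.42), ncam3 (3.93 ± 0.75), mymk and slc9a5 (3.77 ± 0.69). The lowest were CFAP65 (-2.38 ± 0.61), foxj1b (-2.27 ± 0.54), kcnh6a (-2.17 ± 0.35), tpx2 (-2.17 ± 0.55), slc6a6a (-2.01 ± 0.41), cdk20 (-1.85 ± 0.50), dyrk2 (-1.81 ± 0.35) and pxnb (-1.78 ± 0.41).

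The number of trained calls was lower without some control libraries. Without untrained_WT replicate 3 there were 335 calls, 327 of them among the 559, and without any other single control 444 to 623. Without replicates 3 and 7 there were 262, 238 of them among the 559, and with the germ-cell score as a covariate there were 199, of which 192 were shared. The germ-cell gene ddx4 was at 18.8 and 11.9 CPM in those replicates and at most 2.57 CPM in any other library. Of the 16 genes with the highest and lowest folds, 10 kept the call under each of 12 alternatives, nr4a3 and actl6b among them, and CFAP65, foxj1b, tpx2, cdk20, pxnb and mymk did not. Of 35 other called genes that the rule took, 10 did, namely lpl, eci1, acads, esrra, myh7ba, myf6, trim63a, ddit3, junbb and per2. The others lost it under at least 1 alternative, among them pparaa, ndufc2, cox5ab, mrpl22, smyhc1, klf15, foxo4, dusp1, myf5, arntl1b, kdrl and tek. Library totals as the only scaling gave 1128 calls, 17.8% of them higher instead of 76.2%, moved the median over all genes from -0.069 to -0.365 and turned 11 list medians, myogenesis and clock among them, and DESeq2 gave 1273, with 55.8% higher. The camera test called 21 lists, 20 higher and germ line and liver lower, and fry 11, all higher. None was left with an estimated correlation (smallest adjusted p = 0.0908, for the ubiquitin ligase list).

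**Figure D3:**
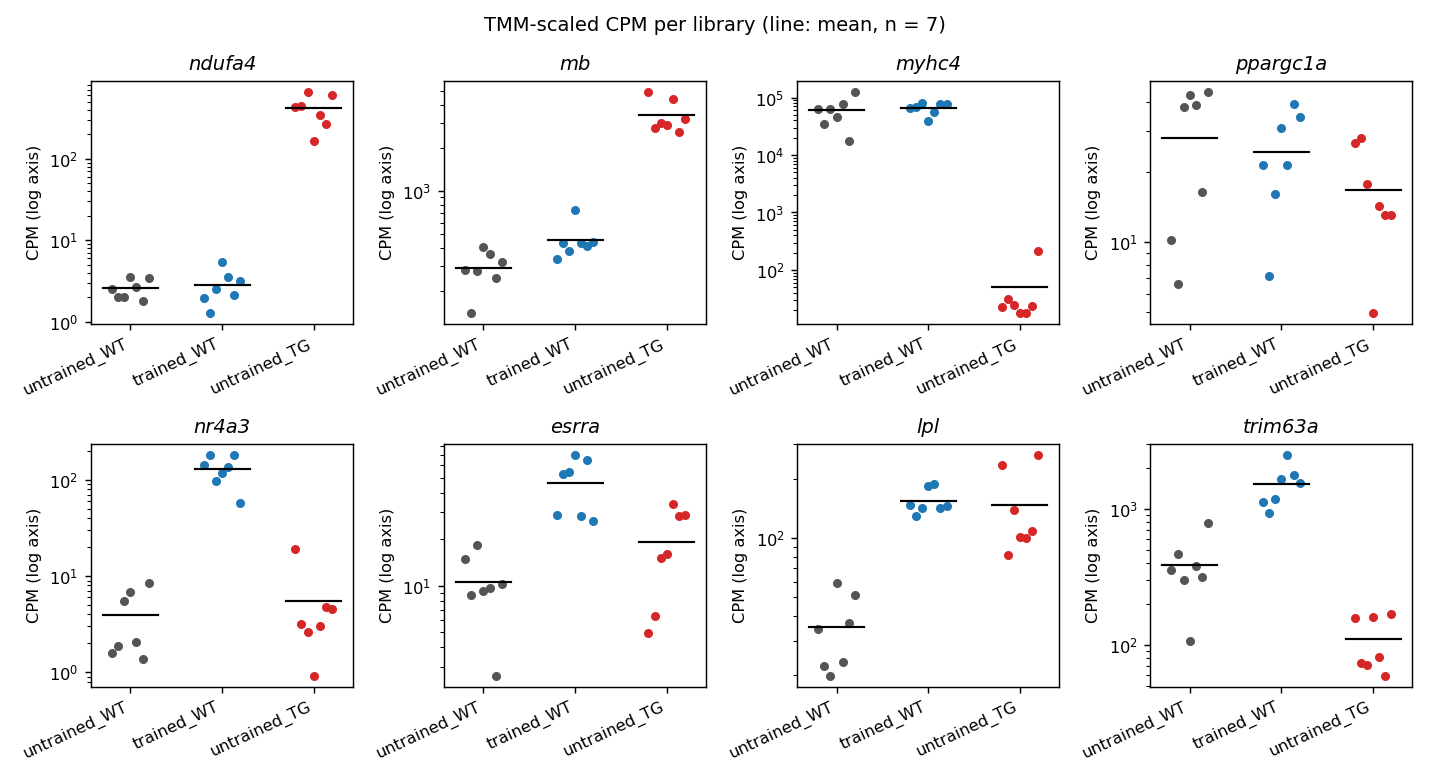
TMM-scaled CPM per library on a logarithmic y axis for 8 named genes in the 3 groups (x axis), with lines at the group means (n = 7). The plots show ndufa4 and mb high in untrained_TG, myhc4 low there, and nr4a3 at 131 CPM in trained_WT against 3.97 in untrained_WT. For ppargc1a the groups overlap.

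The direct comparison of untrained_TG with trained_WT called 7887 genes, 3632 higher and 4255 lower in the transgenic group. It tests where both conditions differed from each other. Respiratory complex genes were higher in untrained_TG in 36 of 37 for complex I, 23 of 24 for complex IV and 16 of 16 for ATP synthase, and fast fibre genes were lower in 28 of 34, the same counts as adjusted over the list alone. With an estimated correlation the adjusted p was 0.224, 0.115, 0.224 and 0.119. The ubiquitin ligase list was lower in 8 of 14 and higher in 1 (fry adjusted p = 1.07e-06), with trim63a at -3.79 ± 0.37, and immediate early genes were lower in 11 of 18, with nr4a3 at -4.59 ± 0.59 (9 and 12 lower adjusted over the list alone, adjusted p = 0.224 and 0.379 with an estimated correlation). For esrra the difference was -1.28 ± 0.41 (adjusted p = 0.0146), and for lpl it was -0.07 ± 0.27 (adjusted p = 0.868). The extremes by the naming rule were cryaa (8.37 ± 0.69), ndufa4 (7.19 ± 0.38), zic2b (7.17 ± 0.64), cpdb (6.95 ± 0.997) and nmrk1 (6.77 ± 0.30) above, and tecrl2b, myha (-10.95 ± 1.25), myhc4 (-10.38 ± 0.76), pvalb1 (-9.88 ± 0.66) and helt below. Mean counts in trained_WT were 2.43 for cryaa, 3.14 for zic2b and 1.43 for cpdb, and in untrained_TG under 1 for tecrl2b and helt, so these folds and their order also depend on the prior count. Camera called 23 lists and fry 24, and no camera call was left with an estimated correlation (smallest adjusted p = 0.115). With library totals only, 30.6% of calls were higher instead of 46.1%.

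Fold changes of untrained_TG and trained_WT share their controls. Across 18947 genes, which are not independent replicates, Pearson's r was 0.375 and Spearman's rho 0.316. Simulated groups with no change gave a mean r of 0.494. There all spread of the fold changes is noise, whereas many genes were called in untrained_TG, which lowers r whatever is shared. The simulated r is therefore no benchmark for the observed one. The covariance was 0.327 against 0.0957 simulated, a difference of 0.231. The simulation drew each gene independently, without differences that many genes of a control library share. The 0.231 therefore cannot be read as covariance beyond the shared controls. With the controls divided, the median r was 0.173, from -0.0522 to 0.298, and the median covariance 0.1625, from -0.0667 to 0.2967. Both comparisons called 180 genes higher, against 78.0 for independent lists, and 46 lower, against 33.4. These values leave out the shared controls, and simulated unchanged groups held 0 shared calls, so neither is a benchmark for the overlap. Another 67 genes were lower in untrained_TG and higher in trained_WT, among them trim63a, klf15 and foxo4, and 18 were the reverse. With divided controls, the medians were 32 shared higher calls against 16.9 for independent lists and 8 shared lower calls against 6.14.

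**Figure D4:**
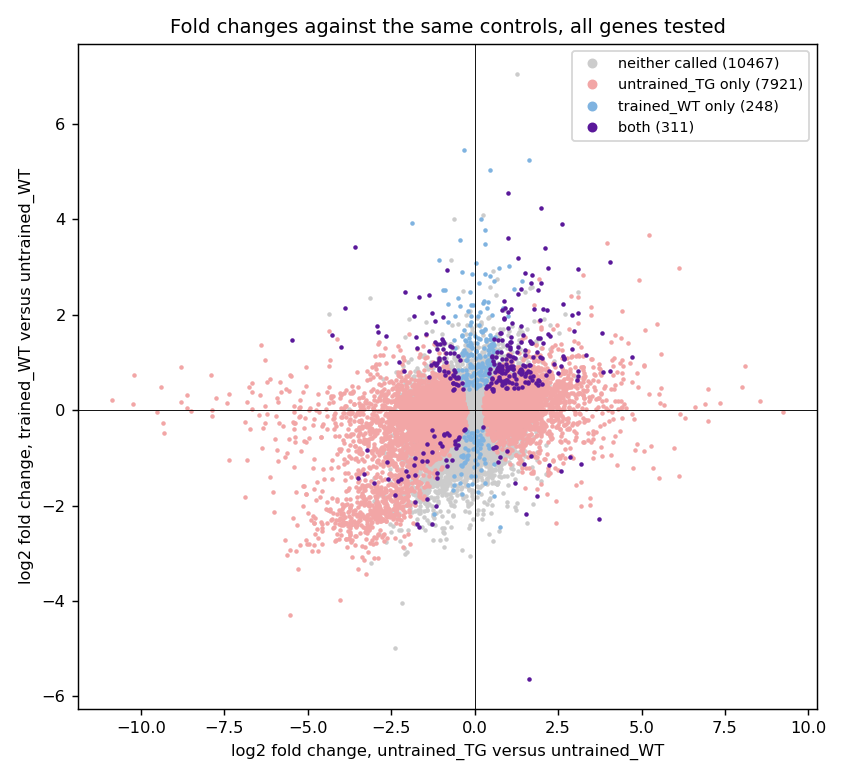
Log2 fold changes of untrained_TG (x axis) and trained_WT (y axis), each against untrained_WT, for all 18947 genes tested, with colours for calls. Genes called in both number 311, in untrained_TG alone 7921 and in trained_WT alone 248.

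The authors' deposited table for untrained_TG versus untrained_WT lists 9082 gene IDs with an adjusted p under 0.05, 3884 higher and 5198 lower, of which 8081 were also called by edgeR, all in the same direction. The authors' deposited table for trained_WT lists 1262, 695 higher and 567 lower, and holds all 559 edgeR calls in the same direction.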

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

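The tests of fast fibre genes, of group differences in germ-cell transcripts and of the transgene construct were chosen after the result was seen. Of 285 groups of 7 libraries examined, 37 held a library far from the others, against a nominal chance value of about 14.2. Most values were CPM without a log, which are often skewed, and the groups share libraries. The excess over 14.2 therefore does not by itself show unusual libraries.

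Among the library measures, untrained_TG replicate 7 had 42.8 M counts, against 63.3 to 78.1 M in the other transgenic libraries. Untrained_WT replicate 7 had a TMM factor of 2.008, against 0.906 to 1.35, and untrained_WT replicate 3 had 24330 detected genes, against 21990 to 22790. Trained_WT replicate 6 had 10.84% of reads with more than 1 alignment, and trained_WT replicate 4 had 23.84% of counts from fast fibre genes. Reads without a feature, which enter no comparison, averaged 9.179% in untrained_TG, above every untrained_WT library (5.02% to 8.09%, exact permutation p = 0.000583).

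In untrained_TG, replicate 7 stood apart with myhc4 at 212.1 CPM, pvalb3 at 51.57, pvalb1 at 10.93, pvalb2 at 31.92 and atp1b1b at 1421 CPM. Replicate 1 had nr4a3 at 19.08 CPM, actl6b at 2.741, mymk at 3.685 and slc9a5 at 0.3812. Replicate 5 had ncam3 at 0.7449 CPM, ndufc2 at 422.6, mrpl22 at 44.09 and tecrl2b at 0.01774, the others having no tecrl2b counts. Replicate 6 had MPV17L at 10.45 CPM, replicate 2 pxnb at 0.6036 and replicate 4 klf15 at 8.153.

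In trained_WT, replicate 3 had myha at 17.78 CPM (the others 1435 to 2303), pygmb at 31.84, mt-co1 at 73230, myh7ba at 21.32 and dyrk2 at 7.511 CPM. Replicate 5 had pvalb1 at 7980 CPM, pvalb2 at 7837 and slc9a5 at 5.124, and replicate 4 had mb at 732.1 CPM. In untrained_WT, replicate 5 had dyrk2 at 52.45 CPM, kdrl at 73.76, myf5 at 8.586 and mtbl at 1.461. Replicate 2 had zic2b at 0.11 CPM, replicate 3 cdk20 at 2.414 and replicate 4 aipl1 at 0.4021.

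For the called genes, 1 of 100 splits of the 14 libraries, the real one, gave as many in each contrast. The real counts were 8232 for untrained_TG versus untrained_WT, 559 for trained_WT versus untrained_WT and 7887 for untrained_TG versus trained_WT, and the highest of the other splits gave 3524, 488 and 3175. No other split drawn gave as many calls, but 100 splits cannot give a share below 1 of 100. Splits that mix the groups also carry the group differences in their spread, which lowers their calls. For trained_WT versus untrained_WT, 335 calls were left without untrained_WT replicate 3 and 199 with the germ-cell covariate. Both lie below the 488 of another split, so the test does not cover those smaller counts. For the lists called by camera with the preset correlation, 58 of 100 splits gave as many as the 15 of untrained_TG versus untrained_WT (highest other 25) and 29 of 100 as many as the 21 of trained_WT versus untrained_WT (highest other 29). Chance cannot be excluded for those list counts. For untrained_TG versus trained_WT, 3 of 100 gave as many as 23, with 25 the highest of the others.

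Fast fibre transcripts were lower in transgenic muscle. Counts taken up by mitochondrial transcripts would lower all other genes by about the same factor. They do not account for a gap between the fast list and the other genes. With mitochondrially encoded and fast genes left out of the scaling, the fast list lay 3.45 log2 units below the median of all genes (difference -3.45). Scaling moves all genes about alike, so this gap was bound to stay and the rescaling itself adds no support. Under it the fast list median was -3.53 against -0.08 for all genes, and 28 members still fell. A smaller share of otherwise unchanged fast fibres stays open. The members that fell spread over an interquartile range of 3.92 log2 units, but members also expressed in other fibres would fall less, so this spread does not exclude it. A switch of the same fibres under the transgene may equally apply, with slow fibre genes at a median of 2.19, and bulk RNA cannot separate these.

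Germ-cell transcripts varied between libraries of a group. Testis tissue carried along with the muscle is a candidate source: a second list of 18 testis genes, 0 of them in the fixed germ line list, followed the germ-cell score over 21 libraries with Pearson's r = 0.95 (permutation p = 1e-05, the smallest 100000 resamples give) and Spearman's rho = 0.88 (p = 1e-05, same test). Without the 2 farthest libraries r was 0.92, and for deviations from group means 0.94. The most abundant gene of that list, hsd11b2, averaged 199 CPM with a minimum of 59, and 2 of the 18 reached 1 CPM in every library. Many of the 18, such as sycp1, dmc1 and spo11, are meiotic genes that would follow the score with germ cells of any source. The correlation therefore does not single out testis or tissue carried along. The score also differed between groups, with 0.06 ± 2.59 in untrained_WT and -3.98 ± 1.02 in untrained_TG (exact permutation p = 0.00117, adjusted p = 0.00351). In trained_WT it was -2.90 ± 2.53 (exact permutation p = 0.0565 and adjusted p = 0.0848 against untrained_WT). Not all markers of reproductive tissue fell in untrained_TG. The fixed germ line and liver list, which also covers ovary, had 5 higher and 3 lower of 22. Among the higher were the vitellogenin genes vtg7 (2.62 log2 units) and vtg3 (1.54) and the egg-coat gene zp3d.1 (5.58), each called under all 12 alternatives. A difference between the groups, such as the sex of the fish, therefore stays open and untested.

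The lens crystallin gene cryaa was at 11.2 CPM in untrained_TG and at most 0.129 CPM in any wild-type library. Lens tissue carried along does not account for it: the 35 other lens genes with counts had a median log2 fold change of 0, and the most abundant of them, bfsp2, reached 1.9 CPM, although bfsp2 itself was higher by 4.1 log2 units. Part of the lens gene carried on the transgene construct may be the source, since the lowest transgenic library had 7.94 CPM (7.73 with TMM factors from all genes, as for bfsp2, against at most 0.132 in wild-type libraries), but the construct is not described in the labels and this cannot be told apart from other differences of the transgenic line.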

How the results depend on the processing

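The alternatives that left out libraries and the one with the germ-cell score were added after seeing the data. In the contrast for which the naming rule took it, no called gene changed direction under the alternatives run, nor did any share past the threshold or the camera direction of any list that camera called. In untrained_TG versus untrained_WT, for which the rule did not take it, CFAP65 was called at -1.72 log2 units, lost the call under 5 of 12 alternatives and turned positive with the germ-cell covariate. Library totals as the only scaling turned 10 list medians for untrained_TG versus untrained_WT, 11 for trained_WT versus untrained_WT and 3 for untrained_TG versus trained_WT, and the trained calls from 76.2% to 17.8% higher. The mitochondrially encoded share in trained_WT, which was not called, went from 0.725 percentage points to slightly below 0 without the 20 most abundant genes in the denominator. RLE scaling turned 1 list median, PGC1a partners in untrained_TG versus untrained_WT, at 0.03. For untrained_TG versus untrained_WT and versus trained_WT, counts of called genes ranged from 6178 to 9677 and from 7117 to 8699 over 12 alternatives. For trained_WT versus untrained_WT, with 559 reported, DESeq2 gave 1273, library totals only 1128, limma-voom with quality weights 978, both untrained_WT libraries 3 and 7 left out 262 and the germ-cell covariate 199. Without untrained_WT replicate 3 there were 335, and without any other single untrained_WT library 444 (replicate 7) to 623 (replicate 5). Without untrained_TG replicate 7 there were 522. Over all 21 pairs of untrained_WT libraries left out, the median was 501 (250 to 742), with 250 to 339 for the 6 pairs that hold replicate 3 and 298 to 742 for the other 15. The cause was not tested.

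With an estimated correlation 0 lists were called in each of the 3 contrasts. For trained_WT versus untrained_WT fry called 11 and camera with the germ-cell covariate called 13, against 21 reported. The correlation of fold changes moved from 0.375 to 0.173 with divided controls and to 0.172 over genes of at least 10 CPM. The higher share of oxidative phosphorylation counts in trained_WT became 0.311 percentage points with medians (adjusted p = 0.0749).

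Replicate numbers did not pair the samples. Of 18 same-numbered pairs of libraries, 4 had deviations correlated above 0.1 (range -0.36 to 0.4), and 2 correlated best with their own number. With the replicate block, 369 genes were called for trained_WT versus untrained_WT, 7270 for untrained_TG versus untrained_WT and 7117 for untrained_TG versus trained_WT.

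Of the called genes that the rule took, 10 of the 16 with the highest and lowest folds and 10 of 35 others kept the call under every one of the 12 alternatives that gave them a value for trained_WT versus untrained_WT, against 16 of 16 and 84 of 102 for untrained_TG versus untrained_WT. Over all of the rule's genes, 140 combinations of a gene and an alternative lost a call and 37 gained one for trained_WT versus untrained_WT, and 34 and 9 for untrained_TG versus untrained_WT. On simulated counts 54 of 100 changes of 1 log2 unit, planted in genes with a mean of at least 50 counts, were recovered for trained_WT versus untrained_WT.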

Other observations

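No test was added for these values, which come from genes the naming rule took; they were put together after the values were seen. The glycogen phosphorylase genes went in opposite directions in transgenic muscle, pygma from 1329 ± 530 to 259 ± 43.5 CPM and pygmb from 8.90 ± 2.74 to 105 ± 47.5 CPM (n = 7 each), and pygma stayed the more abundant. The list of glycolysis genes split 16 lower to 6 higher. Among myosin genes, myhc4 changed by -10.25 and myh7ba by 2.60 log2 units. Reads shared between close paralogs were not examined.

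The genes trim63a and klf15 were higher in trained_WT and lower in untrained_TG, though klf15 lost its trained call under 2 alternatives and its transgenic call under 1. The ubiquitin ligase gene trim63a averaged 387 ± 208 CPM in untrained_WT, 1529 ± 522 in trained_WT and 111 ± 49.5 in untrained_TG, and klf15 9.55 ± 5.26, 25.1 ± 6.51 and 4.62 ± 1.69 (n = 7 each). The ciliary regulator foxj1b and the potassium channel gene kcnh6a showed the reverse order (foxj1b lost its call in trained_WT under 4 alternatives), with kcnh6a at 17.0 ± 9.39, 3.76 ± 1.37 and 48.9 ± 19.4 CPM.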
